A study of Mus musculus with 13 samples.

How the data were processed

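AGO CLIP was performed on cortex of C57BL6 mice aged 7 to 8 weeks, in sham (4), MCAO contralateral (4) and MCAO ipsilateral (5) libraries. AGO was immunoprecipitated after ultraviolet crosslinking, high and low molecular weight complexes were pooled, and fragments were cloned by BrdU-CLIP, a method that captures the copied fragments by an incorporated base analog. Both deposited tables hold counts, whole numbers of tags per mature miRNA and per AGO peak, not normalized. The submitters named the mm10 build and the aligner Novoalign, without a version; the peak caller and the collapsing of duplicate tags are not given in the sources used here. Every miRNA in the table had at least 50 tags over the 13 libraries and every peak at least 3, so features below those totals appear to have been left out before the tables were made. If duplicates were not collapsed, tags are not independent molecules; intervals and limits given for shares cover counting error only.

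The miRNA table held 1705 miRNAs and 408129 tags. The peak table held 18285 peaks, of which 1 without a position (44 tags) was left out, leaving 395152 tags in 18284 peaks with 4652 gene names. Peak position, gene and region are those of the deposited table. Transcript sequence under peaks was read from GENCODE release M21 (GRCm38, the same assembly as mm10), and 11728 peaks with at least 50 bases of transcript sequence were searched for seed sites of 44 miRNA families: matches to miRNA positions 2 to 8, or 2 to 7 followed by A. Site enrichment was computed in 6612 3'UTR peaks against 20 windows per peak from the same 3'UTR, with 20 shuffled motifs per family.

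Peak tags per library were 71027, 22818, 17918 and 26584 (sham replicates 1, 2, 3, 5), 65781, 25249, 7950 and 11798 (contralateral 1, 2, 4, 5) and 64216, 34820, 36106, 7105 and 3780 (ipsilateral 1 to 5). The miRNA tags in the same order were 55912, 39788, 24906 and 29930, then 61708, 36993, 13117 and 14635, then 34758, 43349, 38050, 11132 and 3851. The median peak had 11 tags over all libraries, which limits single peaks most. In data simulated at these depths, edgeR recovered 85%, 70% and 74% of miRNAs changed 2-fold in the 3 comparisons, but 0% of peaks. The miRNA values assume counts free of background; any background in the miRNA counts would dilute a change and lower this recovery. Peaks changed 4-fold were recovered in 0%, 0% and 2.22% of cases, so the absence of calls for single peaks, those of Slc1a2 included, says little. For exonic gene sums it recovered 39.2%, 44.3% and 31.8% at 2-fold and 98.3%, 96.8% and 85.9% at 4-fold. All these percentages are of changed features that passed the filter, and the changed features were drawn from the most covered. In each run 100 features were changed 2-fold and 100 others 4-fold at once, with 1441, 1429 and 1408 miRNAs run. So many changes loosen the adjusted threshold. Recovery where only a few features change was not simulated and would be lower. Of 100 genes changed 2-fold, 51, 61 and 44 passed the filter and 20, 27 and 14 were recovered. Of 100 genes changed 4-fold, 58, 61 and 61 were recovered. Seed family sums changed 1.3-fold were recovered in 47%, 44% and 39% of cases.

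The planned tests, fixed before the data were examined, were edgeR 4.0.16 quasi-likelihood tests on miRNAs and on peaks, with TMM factors, filterByExpr, all 13 libraries in 1 fit, two-sided, and Benjamini-Hochberg adjusted p under 0.05. The filter kept 1427 miRNAs (94.8% of tags) and 238 peaks (25.4% of tags), with biological coefficients of variation of 0.206 and 0.901. Fixed lists (22 of miRNAs, 16 of genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists needed 2 miRNAs or 3 peaks. The gene lists were glutamate transport and metabolism, glutamate receptors, GABA signalling, known miR-29 targets, the miRNA pathway, immediate early genes, heat shock and unfolded protein response, hypoxia response, apoptosis regulators, inflammatory response, and markers of astrocytes, neurons, the oligodendrocyte lineage, microglia and myeloid cells, vascular cells and blood. The planned test of seed families needed 10 tested peaks per family, which no family reached under the filter. DESeq2 1.42.0 was the alternative test.

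Because the planned edgeR feature tests called nothing in the main fit, further tests were chosen after seeing the data. Several routes were tried: set tests without a filter, sums over all peaks of a gene, sums over exonic peaks of a gene (63.1% of tags in tested genes), sums over the exonic peaks of a list (12 lists with at least 10 peaks) or of a seed family (44 families), and the family sums in 3'UTR peaks alone. The list and family sums were tested by edgeR with the exonic tags of a library, or its 3'UTR tags, as library size, and Benjamini-Hochberg adjustment within lists or families. None of the added tests was adjusted for the number of routes. Without a filter, camera called 2, 6 and 0 of 14 gene lists in the 3 comparisons, none with an estimated correlation, and 0 of 44 seed families in each. Sums over all peaks of a gene gave no call, and with the replicate block they gave Hspa1b in both ipsilateral comparisons (adjusted p = 0.00776 and 0.0374 by edgeR over 610 genes). Shares were compared by exact permutation tests (two-sided, pseudocount 0.5), for which the smallest p is 0.0159 against the ipsilateral group and 0.0286 between the others. Intervals of shares are Wilson intervals at 95%, and correlations used 100000 permutations. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

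Each set of replicates was prepared together from 1 day of surgery per the labels, so the replicate number pairs samples across groups. Deviations from group means were correlated more within a number than between numbers (median r over 11 pairs 0.183 for exonic genes and 0.0929 for miRNAs, against -0.08 and -0.04 over 45 other pairs). A fit with the number as a block was therefore run beside each test. No pair of libraries within a group was close enough to be a copy (chi-square per degree of freedom 1.14 to 2.68 for miRNAs and 2.14 to 15.6 for peaks over 22 pairs each). Other alternatives were median-of-ratios factors, total counts, no filter, only the 2 groups compared, and each library left out in turn; after seeing the data, the fit without the libraries of replicate 1 was added. Genes were named by a rule fixed beforehand: the called features with the smallest p, up to 10 miRNAs and 12 peaks per direction, always miR-29a-3p, miR-29b-3p, miR-29c-3p and the Slc1a2 peaks, and where fewer than 3 passed, up to 3 of the smallest p named as not passing. Hspa1a, Snap25, Sipa1l1, Egr1, Sparc and the gene sums of Slc1a2 were named after their values were seen.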

Results

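Argonaute (AGO) proteins carry microRNAs (miRNAs) to their target RNAs, and AGO CLIP sequences the RNA fragments that ultraviolet light has crosslinked to AGO. Each sequenced fragment is called a tag here. Cortex of C57BL6 mice aged 7 to 8 weeks was taken in 3 groups: sham surgery (4 libraries), the contralateral hemisphere after occlusion of the middle cerebral artery (MCAO, 4 libraries) and the ipsilateral, ischemic hemisphere (5 libraries). The artery was occluded for 35 min and tissue was taken after 3 h of recovery. Each library gave 2 readouts, tags on mature miRNAs and tags in AGO peaks on other RNAs. Depth was low and uneven. Peak tags ranged from 3780 in ipsilateral replicate 5 to 71027 in sham replicate 1, and miRNA tags from 3851 in ipsilateral replicate 5 to 61708 in contralateral replicate 1. The purpose stated in the title of the series was the acute regulation of glutamate homeostasis in the brain after ischemic stroke. For that purpose the glutamate transporter gene Slc1a2 (GLT-1) was named before the data were examined. The miR-29 family was also named beforehand, a choice that does not follow from that purpose.

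Of 18284 AGO peaks, 42.9% lay in 3'UTRs, 21.5% in coding sequence (CDS) and 20.9% in introns. For some of 44 seed families, 3'UTR peaks held seed sites more often than other windows of the same 3'UTRs: 23 families had an interval above 1 and 5 below 1, and for 9 no shuffled motif reached the ratio of the family. For miR-137 sites the ratio was 2.73 (95% bootstrap interval 2.21 to 3.32), for miR-124, a neuronal miRNA, 2.40 (2.04 to 2.84), for the miR-26 family 2.18, for the miR-30 family 2.15, for the miR-29 family 1.63 (1.32 to 1.99) and for the let-7/miR-98 family 1.60. These 6 families were among the 9, with 20 shuffled motifs of the same base composition each. Sites of miR-7 (0.788, 0.606 to 0.983) and miR-24 (0.654, 0.502 to 0.812) were less frequent in peaks than in other windows, but so were their shuffled motifs (medians 0.621 and 0.895). The 3 libraries of replicate 1 stood apart from the others: 50.4% to 60.4% of their peak tags lay in introns and between genes, against 17.5% to 44.2% in the other 10 libraries (exact permutation p = 0.00699, two-sided). Because of this difference, list and family totals below are given as shares of the tags in exonic peaks.

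**Figure D1:**
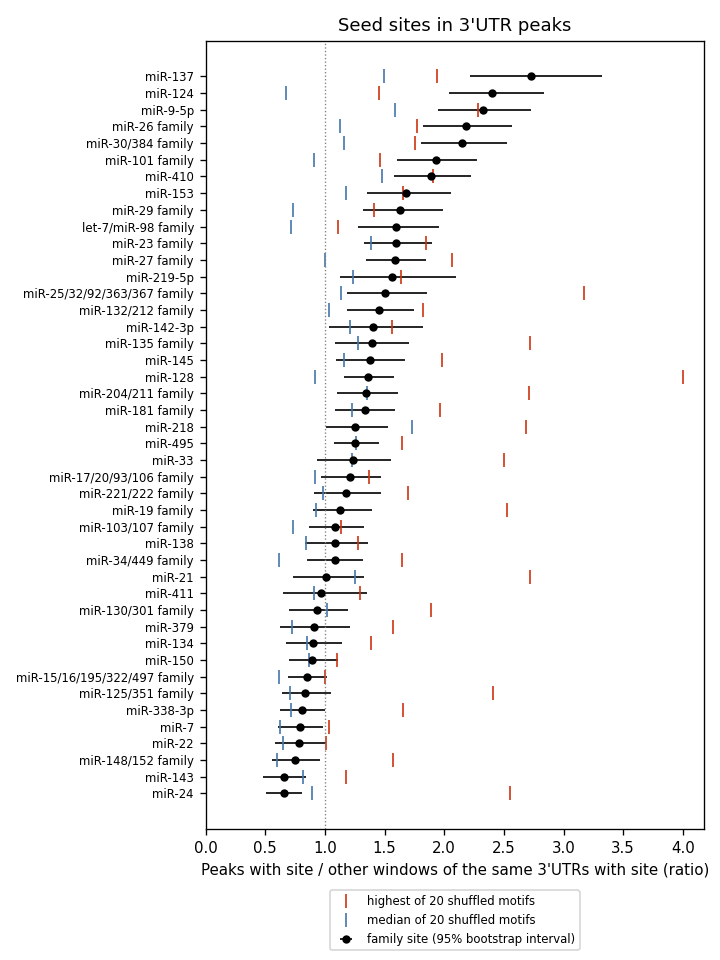
Ratio of the share of 3'UTR peaks with a seed site to the share of other windows of the same 3'UTRs, for 44 seed families. Points are family sites with 95% bootstrap intervals, and the marks give the median and the highest of 20 shuffled motifs per family; miR-137 lies at 2.73 and the miR-29 family at 1.63.

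**Figure D2:**
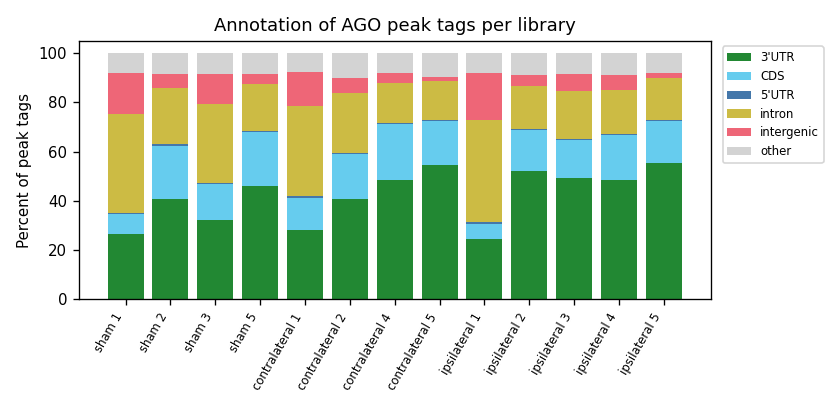
Percent of AGO peak tags in each annotated region, by library. The replicate 1 library of each group has 50.4% to 60.4% of its tags in introns and between genes, above every other library.

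In the main fit, the edgeR tests of single miRNAs and single peaks called no feature in any of the 3 comparisons. DESeq2 called 1 peak, in ipsilateral against contralateral cortex, and no miRNA. With total counts only, edgeR called 1 peak in ipsilateral against sham cortex. What follows on genes, gene lists and seed families pools tags over peaks. These pooled tests were chosen after the edgeR tests had been seen to call nothing in the main fit.

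The comparison of ipsilateral with sham cortex sets AGO tags after ischemia against those in uninjured brain. The data hold no separate measure of RNA level. In every comparison here, tags summed over a gene or gene list therefore cannot tell a changed RNA level from changed AGO binding. AGO tags on Hspa1b and Hspa1a, the inducible 70 kDa heat shock proteins, were almost confined to ipsilateral libraries. Hspa1b had 127 exonic tags in the 5 ipsilateral libraries and 1 in the 4 sham libraries, a ratio of shares of 111 (95% counting interval 19.6 to 4423), and Hspa1a had 33 and 0. Ipsilateral replicates 2 to 5 held 17.8 to 40.9 tags on these 2 genes per 10000 exonic tags, but ipsilateral replicate 1 held 0, which allows up to 1.80 per 10000. Tags on Camk2a, the alpha subunit of the abundant neuronal kinase CaMKII, were lower: 56.5 ± 12.6 per 10000 exonic tags (SD, n = 5) against 102 ± 11.3 (n = 4). In 3'UTR peaks that hold a miR-29 seed site, ipsilateral libraries had 1.68 ± 0.126% of 3'UTR tags (SD, n = 5) against 2.35 ± 0.271% in sham (n = 4), and all 5 ipsilateral libraries (1.55% to 1.89%) lay below all 4 sham libraries (lowest 2.13%).

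Tested as gene sums over exonic peaks, edgeR called Hspa1b higher (log2 fold change 6.24, SE 1.18, adjusted p = 0.0148) and Camk2a lower (log2 fold change -0.89, SE 0.19, adjusted p = 0.0316). The fitted fold change of Hspa1b depends on the prior count, since sham held 1 tag, and by exact permutation of its share Hspa1b had p = 0.0635 and Camk2a p = 0.0159. Hspa1a is a near copy of Hspa1b, so tags may be shared between the pair, and was not tested by itself under the filter. In fits with 1 library left out Camk2a ranged from -0.948 to -0.749 and Hspa1b, where tested, from 5.81 to 7.73 (without sham replicate 5, which held its only sham tag), and the calls did not always hold. Hspa1b missed the threshold without sham replicate 1 (adjusted p = 0.0843), sham replicate 2 (0.0640) or sham replicate 5 (0.0766), and it failed the expression filter and was not tested without ipsilateral replicate 2, 3, 4 or 5. Camk2a missed it in 11 of 13 fits with 1 library left out: without sham replicate 1 (adjusted p = 0.205), 2 (0.0670), 3 (0.0993) or 5 (0.0992), contralateral replicate 1 (0.0533), 2 (0.0992) or 4 (0.0686), or ipsilateral replicate 2 (0.0702), 3 (0.154), 4 (0.1001) or 5 (0.114). Without the expression filter its adjusted p was 0.211. With replicate number as a block, edgeR called 4 genes in place of 2: Hspa1b, Pafah1b1 and Snap25 higher and Camk2a lower. DESeq2 called 5 genes.

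Among gene lists fixed before the data were examined, the summed tags of the heat shock and unfolded protein response list rose in ipsilateral against sham libraries, although only 7 of its 15 genes with tags had a higher share and 8 a lower one. Together they held 0.695 ± 0.171% of exonic tags (SD, n = 5) against 0.356 ± 0.0698% (n = 4), a log2 fold change of 0.89 (SE 0.19, edgeR on tag sums, adjusted p = 5.0e-04 over 12 lists; exact permutation p = 0.0159, the smallest the design allows, and 0.0952 when adjusted over the lists, where 4 lists at that smallest p are needed to pass). This call rests on Hspa1a and Hspa1b: without them the log2 fold change was 0.28 (adjusted p = 0.257). Of 5 members tested as genes, 1 passed, also when adjusted over the list alone. With a TMM scaled library size the adjusted p was 0.0511. Immediate early genes, which neurons induce with activity and stress, had 0.760 ± 0.253% against 0.564 ± 0.0522% and did not pass (log2 fold change 0.40, adjusted p = 0.114). Without ipsilateral replicate 1 they passed (0.60, adjusted p = 1.3e-04). No other list passed. Glutamate transport and metabolism genes had a log2 fold change of -0.07 (SE 0.13, adjusted p = 0.722; 0.16 with all peak tags as library size), glutamate receptors -0.19 (adjusted p = 0.312), GABA signalling 0.32 (adjusted p = 0.0894), oligodendrocyte lineage markers -0.36 (adjusted p = 0.0636), astrocyte and neuron markers 0.00 and -0.13, known miR-29 targets -0.15, miRNA pathway genes -0.23, apoptosis regulators -0.12 and hypoxia response genes 0.01. Inflammatory response genes and markers of microglia, vascular cells and blood had 1 to 3 genes with exonic tags and were not summed. Of 12 neuron markers tested as genes 1 passed, or 2 when adjusted over the list alone.

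Of 44 seed families tested in 3'UTR peaks, edgeR without the replicate block called the miR-29 family alone, as lower (log2 fold change -0.49, SE 0.095, adjusted p = 0.00355; exact permutation p = 0.0159, not adjusted over families). With the block it called 3: miR-29, miR-124 and miR-7. Without the block miR-7 (-0.43, SE 0.18, adjusted p = 0.321) and miR-124 (-0.41, SE 0.16, adjusted p = 0.289) fell by nearly as much and did not pass. The largest rise was that of miR-379 (0.25, adjusted p = 0.662). For miR-29, DESeq2 gave -0.49 (adjusted p = 0.00568). The call remained without each of the 13 libraries in turn (adjusted p 0.00115 to 0.0235). It was lost when the library size was all peak tags (-0.15, adjusted p = 0.821). It was also lost with a TMM scaled library size, where the value was larger but less certain (-0.62, SE 0.24, adjusted p = 0.250). Over all exonic peaks the log2 fold change was -0.38 (SE 0.085, adjusted p = 0.0199), and -0.41 with the replicate block (adjusted p = 0.00808). That wider call was lost without sham replicate 1 (adjusted p = 0.105), sham replicate 2 (0.0624), ipsilateral replicate 2 (0.0668) or ipsilateral replicate 3 (0.0782). The most covered miR-29 site peak lay in the 3'UTR of Sparc, which encodes a secreted matrix protein (mm10 chromosome 11, 55395404 to 55395483). Pooled over libraries it had 26.1 tags per 10000 in sham, 27.8 in contralateral and 21.4 in ipsilateral cortex. Summed over its exonic peaks, Sparc varied widely between libraries (31.3 ± 19.3 in sham, 27.3 ± 18.5 in ipsilateral) and did not differ (exact permutation p = 0.730). The 3'UTR site of Slc1a2 (chromosome 2, 102788503 to 102788582) had 6.10, 4.35 and 3.46 tags per 10000, pooled from 37, 23 and 24 tags. The pooled values carry no measure of spread and do not by themselves show a fall. In CDS peaks with a site the share did not differ by exact permutation against sham (-0.08, p = 0.460) or contralateral (0.10, p = 0.571). Of 197 genes with a site peak, 129 had a lower pooled share in ipsilateral than in sham libraries, and 118 a lower one than in contralateral libraries. The same count over all exonic genes was not made, so neither can be read as an excess.

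**Figure D3:**
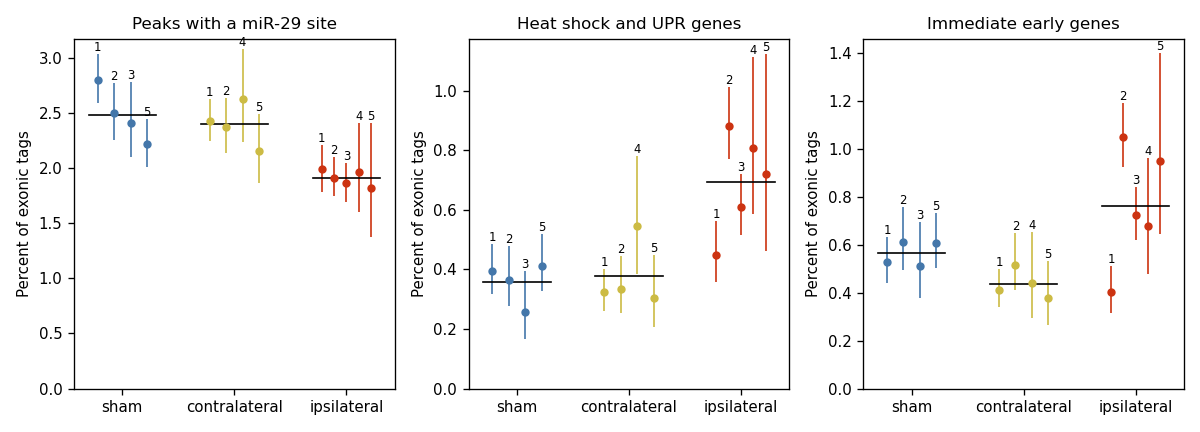
Percent of exonic tags per library in peaks with a miR-29 site, on heat shock and unfolded protein response genes and on immediate early genes. Points are libraries labelled by replicate number with 95% Wilson intervals, and lines are group means; for miR-29 sites all 5 ipsilateral libraries lie below the lowest control library at 2.16%.

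**Figure D4:**
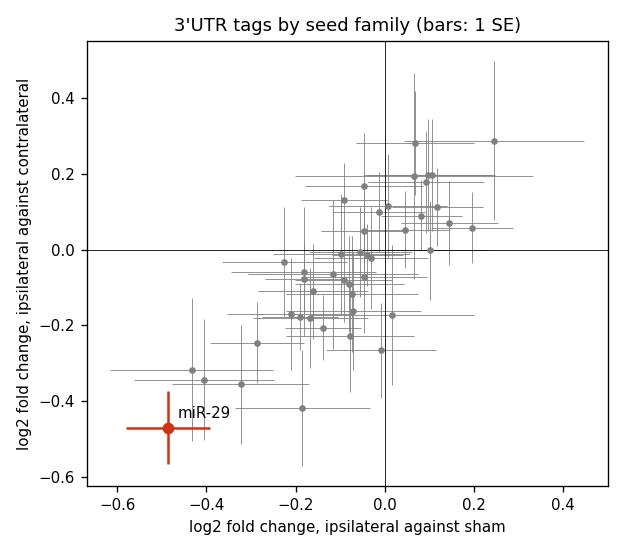
Log2 fold change of 3'UTR tags for 44 seed families in ipsilateral against sham (horizontal) and against contralateral cortex (vertical). Bars are 1 SE; the miR-29 family lies at -0.49 and -0.47.

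The miRNAs themselves did not pass. In ipsilateral against sham libraries miR-29a-3p had a log2 fold change of -0.53 (SE 0.36), miR-29b-3p -0.15 (SE 0.34) and miR-29c-3p -0.999 (SE 0.44), each with an edgeR adjusted p of 1.00. Most miRNAs in the table lay near a common floor, and miR-29c-3p was at 0.649 times the library median, so its value says little about its level; miR-29a-3p was at 3.00 and miR-29b-3p at 6.15 times the median. Of 1427 miRNAs tested, edgeR called 0, with 35 at an unadjusted p under 0.05, and DESeq2 called 0, with 13. The smallest p values, none of which passed, belonged to miR-5709-3p (log2 fold change 0.79) and miR-7029-3p (0.59) among the higher and to miR-5123 (-0.82) and miR-6991-5p (-0.89) among the lower. Of 238 peaks tested, edgeR called 0, with 5 at an unadjusted p under 0.05, and DESeq2 called 0, with 9. The smallest p values belonged to intronic peaks of Tenm4 (3.43) and Mir30d (3.01), and to peaks of Rn45s (-1.54) and Gria3 (-1.60), none of which passed. Without ipsilateral replicate 5 the Tenm4 value was -0.84 and the Mir30d value -0.14. The 11 tested Slc1a2 peaks had log2 fold changes from -0.46 to 0.89, and none passed. As an exonic gene sum Slc1a2 had 235 ± 39.7 tags per 10000 in ipsilateral and 248 ± 18.1 in sham libraries (log2 fold change -0.11, SE 0.14, adjusted p = 0.833). No miRNA list of 19 tested passed with camera. Of 5 gene lists with enough tested peaks, camera with a preset correlation called astrocyte markers (14 peaks, median log2 fold change 0.28, adjusted p = 0.0270) and neuron markers (6 peaks, median -0.15 but mean 0.27, adjusted p = 0.0270) higher. Neither held (adjusted p = 0.413 for both with an estimated correlation), and with the replicate block 0 lists passed. Of the 14 astrocyte marker peaks, 11 were those of Slc1a2.

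The comparison of ipsilateral with contralateral cortex sets the ischemic hemisphere against the other hemisphere of operated animals. Camk2a was again lower (log2 fold change -0.95, SE 0.19, adjusted p = 0.0293 by edgeR on gene sums), at 56.5 against 110 ± 19.5 tags per 10000 (n = 4). Hspa1b had 127 tags against 5, a log2 fold change of 4.17 (SE 0.97) that did not pass (adjusted p = 0.0561; exact permutation p = 0.0952). It passed with the replicate block (3.96, adjusted p = 7.3e-04), without ipsilateral replicate 1 (4.54, adjusted p = 6.0e-05) and without sham replicate 2 (4.12, adjusted p = 0.0474). With the block edgeR called 5 genes in place of 1: Hspa1b and Rtn1, which encodes a reticulon of the endoplasmic reticulum, higher, and Camk2a, Sptbn1 and Sipa1l1 lower. DESeq2 called 10. The Camk2a call was lost without sham replicate 5 (adjusted p = 0.0520), contralateral replicate 1 (0.221), contralateral replicate 2 (0.0896), ipsilateral replicate 3 (0.0666) or ipsilateral replicate 5 (0.0689), and with only the 2 groups in the fit (0.0505).

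By edgeR on list sums, 6 of 12 gene lists passed. The list values that follow are of summed tags and not of each member. Heat shock and unfolded protein response genes rose (log2 fold change 0.93, SE 0.20, adjusted p = 5.2e-04; 0.38 and adjusted p = 0.0716 without Hspa1a and Hspa1b; exact permutation p = 0.0317). Immediate early genes rose (0.77, SE 0.20, adjusted p = 0.00209, and exact permutation p = 0.0635), with 18 of 22 members at a higher share. Egr1, a transcription factor of this class, had 65 tags against 10 (9.38 and 1.89 per 10000 exonic tags, pooled). The mean share of the list was also lower in contralateral (0.436%) than in sham libraries (0.564%). In 1 of 4 same-number pairs the ipsilateral share was the lower one (0.402% against 0.412% in replicate 1). The summed tags of GABA signalling genes rose (0.48, SE 0.14, adjusted p = 0.00510), with 8 of 14 members at a higher share and 6 at a lower one. The summed tags of oligodendrocyte lineage markers fell by 0.44 on the log2 scale (SE 0.14, adjusted p = 0.00806), those of glutamate receptors by 0.36 and those of known miR-29 targets by 0.30. In these lists 8 of 8, 9 of 14 and 17 of 24 members with tags had a lower share. Tested as genes, 0 of 3, 0 of 6 and 0 of 10 members passed, also when adjusted over the list alone. The adjusted p was 0.0212 for glutamate receptors and 0.0401 for known miR-29 targets, and the latter became 0.0816 with the replicate block. Outside replicate 1 glutamate receptors no longer passed (-0.27, adjusted p = 0.149), and miRNA pathway genes passed (-0.43, adjusted p = 0.0298). By exact permutation adjusted over the lists, no list passed against contralateral cortex (smallest adjusted p = 0.0635). When the library size was all peak tags, 0 lists passed. Of the heat shock genes and of the immediate early genes tested, 1 each passed when adjusted over its list alone and 0 over all genes; of 12 neuron markers 3 and 1 did. miRNA pathway genes (-0.29), neuron markers (-0.19), astrocyte markers (-0.19), apoptosis regulators (-0.29) and hypoxia response genes (0.07) did not pass. Glutamate transport and metabolism genes did not pass (-0.23, SE 0.13, adjusted p = 0.139), but passed in 3'UTR peaks alone (-0.33, adjusted p = 0.0299). With 1 library left out the exonic value ranged from -0.291 to -0.0838. Contralateral replicate 5 stood apart at 4.93% of exonic tags, against 3.27% to 3.54% in the rest of its group. Slc1a2 held 1452 of the 1931 contralateral and 1628 of the 2268 ipsilateral exonic tags of this list. For known miR-29 targets the list totals were 2327 and 2556. Neither list was summed without Slc1a2. In 3'UTR peaks edgeR without the block again called the miR-29 family alone, and with the block miR-29, miR-338-3p and miR-7 (miR-29 without the block -0.47, SE 0.097, adjusted p = 0.00638; exact permutation p = 0.0159), at 1.68 ± 0.126% against 2.35 ± 0.194% of 3'UTR tags (n = 4). Without the block miR-338-3p fell by nearly as much (-0.42, SE 0.15) and did not pass (adjusted p = 0.277). The largest rise was that of miR-379 (0.29, adjusted p = 0.532). The miR-29 call was lost with all peak tags as library size (-0.44, adjusted p = 0.991), with TMM scaling (-0.53, adjusted p = 0.971) and with matches to positions 2 to 8 only (-0.33, adjusted p = 0.143). Over all exonic peaks it did not pass (-0.32, adjusted p = 0.0942; 0.0495 with the replicate block, and 0.0136 without contralateral replicate 5).

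Of 1427 miRNAs edgeR called 0, with 52 at an unadjusted p under 0.05, and DESeq2 called 0, with 29. miR-505-5p (0.94), miR-30d-5p (1.34), miR-6991-5p (-0.94) and miR-8097 (-0.95) had the smallest p values and did not pass. The log2 fold changes of miR-29a-3p, miR-29b-3p and miR-29c-3p were -0.33, 0.09 and -0.21. Of 238 peaks edgeR called 0, with 6 at an unadjusted p under 0.05, and DESeq2 called 1, a 3'UTR peak of Impact, a regulator of translation (chromosome 18, 12991492 to 12991571; edgeR log2 fold change 4.30, SE 1.34, adjusted p = 0.585; DESeq2 4.36, adjusted p = 0.0232). Without ipsilateral replicate 1 the edgeR adjusted p of this peak was 0.00802. Among lower peaks, those of Malat1 (-2.44) and Rn45s (-1.41) had the smallest p values and did not pass. The 11 Slc1a2 peaks ranged from -1.01 to 0.49 and none passed. The Slc1a2 gene sum was -0.27 (SE 0.14, adjusted p = 0.394). Camera with a preset correlation called glutamate transport and metabolism (median -0.40, adjusted p = 0.00971), known miR-29 targets (-0.42, adjusted p = 0.00971) and astrocyte markers (-0.40, adjusted p = 0.0107) lower. None held (adjusted p = 0.444 for each with an estimated correlation). Slc1a2, with 11 tested peaks (median -0.42), belongs to all of these lists, so they share its peaks and are not separate results.

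The comparison of contralateral with sham cortex asks whether the uninjured hemisphere of operated animals differs from that of sham animals. No gene list or seed family passed by tag sum. miR-29 sites held 2.35% of 3'UTR tags in both groups (log2 fold change -0.02, SE 0.097, adjusted p = 0.976), heat shock genes -0.04 and immediate early genes -0.37 (SE 0.20, adjusted p = 0.518). Of 1427 miRNAs edgeR called 0, with 43 at an unadjusted p under 0.05, and DESeq2 called 0, with 20. miR-7646-5p (0.98), miR-7016-3p (0.88), miR-1982-5p (-0.89) and miR-3104-3p (-0.78) had the smallest p values. miR-29a-3p, miR-29b-3p and miR-29c-3p had log2 fold changes of -0.20, -0.25 and -0.79, and none passed. Of 238 peaks edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called 0, with 5; peaks of Malat1 (1.51) and Syt1 (1.33) among the higher, and an intergenic peak on chromosome 13 (-2.16) among the lower, were among the lowest in p and did not pass. Of exonic gene sums edgeR called 0, with 8 at an unadjusted p under 0.05, and DESeq2 called 0, with 6; Psd3 (0.69), Pip5k1c (0.92), Rtn1 (-0.92) and Map2k4 (-1.04) were lowest in p. The 11 Slc1a2 peaks ranged from -0.04 to 1.40, and the gene sum was 0.15 (SE 0.15, adjusted p = 0.958). Camera with a preset correlation called 4 lists higher: astrocyte markers (0.62, adjusted p = 2.1e-05), glutamate transport and metabolism (0.62, adjusted p = 2.3e-05), known miR-29 targets (0.66, adjusted p = 2.3e-05) and neuron markers (0.91, adjusted p = 0.00106). None held (adjusted p = 0.116 for each with an estimated correlation). Slc1a2, with 11 tested peaks (median 0.66), belongs to the astrocyte, glutamate transport and known miR-29 target lists. These lists share its peaks and are not separate results. Without contralateral replicate 5, 1 list passed.

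The comparisons against sham and against contralateral cortex share the ipsilateral libraries, so shared changes arise without any effect. No miRNA or peak was called in both. Of the exonic genes, Camk2a was called in both; simulated data with no effect gave 0, and so did the data with the ipsilateral libraries split between the comparisons. The covariance of the log2 fold changes was 0.255 over genes against 0.0867 simulated, and 0.184 with that split. For miRNAs it was 0.0388 against 0.0470, and for peaks 0.286 against 0.456 and 0.0201 with the split. Across 31 seed families no relation passed adjustment between the change of the lead miRNA and the median change of its site peaks in ipsilateral against sham cortex (Pearson r = 0.04, permutation p = 0.843; Spearman rho = -0.05, permutation p = 0.783), nor against contralateral cortex (r = 0.23, permutation p = 0.215; rho = 0.36, permutation p = 0.0460) or in contralateral against sham cortex (r = -0.03, permutation p = 0.866; rho = -0.09, permutation p = 0.645). The adjusted p of Pearson r over the 9 relations computed was 0.485 or higher for these 3, the Spearman p values were not adjusted, and without the 2 farthest families r was 0.00, 0.22 and -0.07. Families are not independent replicates. Most had only 1 or 2 tested peaks, so a relation could have been missed.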

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

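The tests of the miR-29 ratio, of depth, of exchanged or wrong labels and of the preparation sets were chosen only after the result was seen. Within each group the library farthest from the others was compared with a critical value for its gap, which chance exceeds in about 1 in 20 groups; 20 values exceeded it among 159 groups of values examined.

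The share of tags at miR-29 sites was lower in all 5 ipsilateral libraries than in the controls, in 3'UTR but not in CDS peaks (3'UTR minus CDS -0.39 against sham and -0.58 against contralateral), and 3 technical explanations were tested on the share over all exonic peaks, not in 3'UTR peaks alone. Against sham, fewer tags on the genes that hold the sites are argued against: relative to other exonic peaks of the same genes the site peaks changed by -0.43 (log2, exact permutation p = 0.0317). Against contralateral this stays open (-0.29, exact permutation p = 0.0635). Base composition is argued against, since 2.27% of 88 shuffled motifs showed a fall as large against sham and 4.55% against contralateral, and so is 1 gene, since leaving out any gene left a value of -0.36 or lower against sham. A decrease of miR-29 bound to AGO may contribute, but the levels of miR-29a-3p, miR-29b-3p and miR-29c-3p did not pass a test. The pattern depends on the library size used, and 5 of 100 splits of the libraries gave as many 3'UTR families against sham, so it stays a hypothesis.

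Ipsilateral replicate 1 held 0 tags on Hspa1a and Hspa1b, while the other 4 ipsilateral libraries held 17.8 to 40.9 per 10000 exonic tags. Low depth is argued against, since 29.7 tags were expected from the lowest of those libraries. A swap with a control library is argued against, since the highest control library held 3.49 per 10000. A single wrong label or a sample from outside the series could explain the absence: the miR-29 site share of this library was 1.99%, below the lowest control at 2.16%, but its interval (1.79% to 2.21%) includes that value, so the label cannot be told apart from a true absence. No biological explanation was tested.

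The libraries of replicate 1 held more intronic and intergenic tags. A few highly covered peaks as the whole explanation are argued against, by a narrow margin. Without the 20 most covered such peaks the lowest of the 3 libraries was at 39.5% and the highest of the others at 38.7% (means 45.5% and 20.8%). Those 20 peaks held 8.55% to 12.2% of peak tags in replicate 1, against 0.636% to 5.51% in the other libraries, so a contribution from them stays open. A difference between preparation sets, which the labels give as separate days of surgery, stays open: the 3 libraries held the 3 highest shares (exact permutation p = 0.00699), but this restates the observation that prompted the test. The set holds 1 library of each group, so the groups are not confounded with it in means over libraries. Values pooled over libraries carry the set unequally. Its library held the most exonic tags of its group in sham (21599) and contralateral cortex (24779). In ipsilateral cortex it held 16680, fewer than replicates 2 (22983) and 3 (22446). Of the exonic Sparc tags the set held 130 of 215 in sham, 96 of 175 in contralateral and 94 of 210 in ipsilateral libraries.

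Of the values beyond the critical value, sham replicate 1 had 71027 peak tags, against 17918 to 26584 in the other sham libraries. Ipsilateral replicate 1 had 24.3% of peak tags in 3'UTRs, 6.46% in CDS and 60.4% in introns and between genes, and 0.492% of exonic tags on apoptosis regulators, against 0.262% to 0.318% in the rest of its group. Contralateral replicate 5 had 5.12% of exonic tags on astrocyte markers, 4.93% on glutamate transport and metabolism genes and 120 tags per 10000 on Sptbn1. Contralateral replicate 4 had 0.547% on heat shock genes, and sham replicate 5 had 1.09% on miRNA pathway genes and 0.571 tags per 10000 on Hspa1b. This Hspa1b value is 1 tag. The other sham libraries held 0, so any tag would have exceeded the critical value. Among miRNAs, miR-7029-3p was at 5.19 per 10000 in ipsilateral replicate 5 and miR-505-5p at 4.57 in contralateral replicate 4. The intronic Tenm4 peak was at 21.2 per 10000 peak tags in contralateral replicate 5 and 294 in ipsilateral replicate 5, and the Mir30d peak at 8.48 and 105.8 in the same libraries. The intergenic peak on chromosome 13 was at 4.71 in contralateral replicate 1 and 11.1 in ipsilateral replicate 1. The other contralateral libraries held 0 there, so any tag in that group would have exceeded the critical value. Rtn1 was at 64.6 per 10000 exonic tags in ipsilateral replicate 5.

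The splits below were not corrected for the number of results they were applied to. Other splits of the libraries into groups of the same sizes were compared with the real groups; up to 100 splits were examined. For miRNAs at an unadjusted p under 0.05, 92 of 100 splits gave as many as the real 35 in ipsilateral against sham (highest other 126), 72 of 100 as many as 52 against contralateral (175), and 30 of 35 as many as 43 in contralateral against sham (129). For peaks the counts were 39 of 100 (real 5, highest other 91), 53 of 100 (6, 93) and 26 of 35 (1, 73). Splits with several times the real count point to a structure of the libraries other than the groups. For exonic gene calls, 9 of 100 splits gave as many as the real 2 (highest other 8), and 8 of 100 as many as the real 1 (highest other 8), so chance was not excluded; in contralateral against sham all 35 gave the real 0. For gene lists, 11 of 100 gave as many as the real 1 against sham (highest other 2), whereas against contralateral only the real split, 1 of 100, gave 6 (highest other 4); in contralateral against sham all 35 gave 0. For seed families over exonic peaks, 4 of 100 gave as many as the real 1 against sham (highest other 2), while against contralateral all 100 gave at least the real 0 (highest other 2) and in contralateral against sham all 35 (highest other 1). For families in 3'UTR peaks, 5 of 100 gave as many as the real 1 against sham and 7 of 100 against contralateral (highest other 2 in each), so chance was not excluded; in contralateral against sham all 35 gave at least 0. Among splits that part as many same-number pairs as the real one, only the real split gave a 3'UTR family call, 1 of 11 against sham and 1 of 13 against contralateral; these are too few for a share under 0.05. The gene list count against contralateral and the exonic family count against sham excluded chance only among splits that ignore this pairing and without correction.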

How the results depend on the processing

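The alternatives without replicate set 1, with other library sizes, in 3'UTR peaks, with stricter seed matches, without Hspa1a and Hspa1b, by gene sums and by tag sums were chosen only after the result was seen. Of 1996 alternative values, 1780 were kept. For tested values this means the same direction and side of the threshold, for counts a similar count, and for medians a value within the SE. Of the rest, 40 no longer passed, 32 newly passed, 110 moved and 34 reversed, 17 of these among 1011 values of single features. Many kept values belong to results that did not pass, so the total does not measure how firm a passing result is. Of 252 counts of miRNA or peak calls, 6 were above 0. The causes were not tested except where named. The planned test of seed families on filtered peaks was not run, since no family had 10 tested peaks.

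Peak calls higher were 1 in ipsilateral against sham with total counts only and with gene sums and the replicate block, and 1 against contralateral with DESeq2 and with gene sums and the block. Exonic gene calls higher against sham were 2 without a filter, 4 with DESeq2, 3 with the block and 5 outside replicate 1; lower calls were 0 without a filter. Against contralateral, higher calls were 2 without a filter, 4 with DESeq2, 2 with the block and 7 outside replicate 1, and lower calls 0, 6, 3 and 3, and 0 with only the 2 groups. Exonic genes gave 1 shared call.

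Peak gene list calls were 0 in all 3 comparisons with an estimated correlation and with fry. Against sham they were 0 with the block and 1 outside replicate 1, and against contralateral 0 outside replicate 1. Gene list sum calls against sham were 0 with TMM scaling and without Hspa1a and Hspa1b, and 2 with only the 2 groups and outside replicate 1; against contralateral they were 0 with all peak tags as library size and 2 with TMM scaling.

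Seed family sum calls against sham were 0 with all peak tags, TMM scaling, outside replicate 1 and with positions 2 to 8 only, and 2 with the block; against contralateral they were 1 in 3'UTR peaks and 3 with the block. 3'UTR family calls were 0 with all peak tags and TMM scaling in both comparisons. With the block they were 3 in both, and against sham 2 outside replicate 1 and 3 with positions 2 to 8.

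With all peak tags as library size, the miR-29 family changed by -0.16 over exonic peaks and -0.15 in 3'UTR peaks against sham and by -0.44 in 3'UTR peaks against contralateral, none passing; contralateral against sham it reversed to 0.19 and 0.29. Heat shock genes (0.93) and immediate early genes (0.88) no longer passed against contralateral. Glutamate transport against sham reversed to 0.16 and heat shock in contralateral against sham to 0.26. With TMM scaling the miR-29 family was -0.52 over exonic and -0.62 in 3'UTR peaks against sham and -0.53 in 3'UTR peaks against contralateral, and heat shock 0.77 against sham; none passed. Without Hspa1a and Hspa1b heat shock was 0.28 and 0.38. In 3'UTR peaks glutamate transport (-0.33) and the miR-29 family (-0.47) passed against contralateral. With positions 2 to 8 only, the miR-29 family was -0.40 over exonic peaks against sham and -0.33 in 3'UTR peaks against contralateral, and no longer passed. With the block it was -0.31 against contralateral and passed, and the Tenm4 peak reversed to -0.27. The block changed no other call of the list sums except known miR-29 targets.

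Outside replicate 1, immediate early genes passed against sham (0.56) and the miR-29 family over exonic peaks (-0.32) did not. Against contralateral, glutamate receptors (-0.27) no longer passed and miRNA pathway genes (-0.43) did. Glutamate transport against sham reversed to 0.0219, heat shock in contralateral against sham to 0.0548 and 3'UTR miR-29 there to 0.0550. miR-29a-3p reversed to 0.20 and miR-29c-3p to 1.03 against contralateral, and miR-29b-3p to 0.0560 against sham. The family relation by tag sums was 0.38 against sham and reversed to 0.27 in contralateral against sham, and to 0.0521 with positions 2 to 8 only.

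With each of the 13 libraries left out in turn, exonic gene calls ranged from 0 to 9 higher and 0 to 3 lower against sham and from 0 to 9 higher and 0 to 5 lower against contralateral. Hspa1b was tested in 9 of these fits, because without ipsilateral replicate 2, 3, 4 or 5 it failed the filter. Peak calls higher against contralateral ranged from 0 to 1, miRNA list calls against sham from 0 to 1, and peak gene list calls from 0 to 4 against sham, 0 to 4 against contralateral and 1 to 4 in contralateral against sham. Gene list sum calls ranged from 1 to 4 against sham, seed family calls from 0 to 4 against sham and 0 to 6 against contralateral, and 3'UTR family calls were 1 against sham in all 13 fits and 1 to 3 against contralateral.

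In the same fits, immediate early genes against sham ranged from 0.143 to 0.603, passing without ipsilateral replicate 1. Glutamate transport against sham ranged from -0.130 to 0.0391, and heat shock in contralateral against sham from -0.186 to 0.0415. The miR-29 family over exonic peaks ranged from -0.430 to -0.308 against sham, from -0.361 to -0.281 against contralateral and from -0.111 to 0.0103 in contralateral against sham, and in 3'UTR peaks from -0.0643 to 0.0649 in the last. Among single features, Tenm4 ranged from -0.838 to 4.11 and Mir30d from -0.138 to 3.87 against sham. miR-29a-3p ranged from -0.667 to 0.0564 against contralateral and from -0.599 to 0.138 in contralateral against sham. miR-29b-3p ranged from -0.384 to 0.0197 against sham and from -0.144 to 0.463 against contralateral, miR-29c-3p from -0.923 to 0.688 against contralateral, and the Slc1a2 gene sum from -0.0340 to 0.301 in contralateral against sham.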

Other observations

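The relation of site enrichment to miRNA level and the hairpin values were chosen only after the data were seen. Across 40 seed families the enrichment of sites rose with the level of the lead miRNA (Pearson r = 0.61, permutation p = 3.0e-05; Spearman rho = 0.60, permutation p = 5.0e-05), and r was 0.51 without the 2 farthest families. Families are not independent replicates. miR-26a-5p had 5118 tags and miR-124-3p 4707, at 34.1 and 29.1 times the library median, and both families had sites enriched over 2-fold. miR-16-5p, at 14.1 times the median, did not follow: sites of its family had a ratio of 0.850 (0.689 to 1.02). miR-137 sites had the highest enrichment, but miR-137-3p had 523 tags, 3.27 times the median.

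The miRNA counts had a broad floor. Of 1705 miRNAs, 1249 (73.3%) lay within 2-fold of the library median and 105 exceeded 3 times that median. The most counted was miR-466i-5p with 5175 tags, ahead of miR-26a-5p, and the 20 most counted miRNAs took 13.3% of tags.

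Peaks over miRNA hairpins differed between libraries in ways the groups do not follow. The Mir16-1 peak (chromosome 14, 61631905 to 61631984) had 21 tags in sham replicate 5, 29 in contralateral replicate 2, 19 in contralateral replicate 4, 40 in ipsilateral replicate 3 and 10 in ipsilateral replicate 4, and 0 to 3 in each of the other libraries. The Mir30d peak (chromosome 15, 68341226 to 68341305) had 40 tags in ipsilateral replicate 5, the shallowest library, and at most 11 elsewhere.

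By tag sums, added after seeing the data, the change of the lead miRNA and of its site tags across 37 families gave r = 0.38 in ipsilateral against sham cortex (permutation p = 0.0192; rho = 0.36, permutation p = 0.0285). The adjusted p over 9 relations was 0.173, so the relation did not pass.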
